A study of Mus musculus with 33 samples.

How the data were processed

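RNA was sequenced from 33 tumours grown from 11 clonal sublines of the mouse melanoma line B2905, with 3 tumours per subline. Per the labels' protocols, 24 sublines were made, 1000000 cells of each were placed under the skin of 5 mice per subline, and tumours were taken at 1000 mm3. Tumours were grouped by the subline in their titles and are named here by subline and title number. Nothing in the labels states which mouse gave which tumour, so p-values measure the spread between these tumours, which come from separate mice only as far as that protocol states. The title numbers run from 222 to 319 in 7 sublines (21 tumours) and from 478 to 578 in 4 sublines (12 tumours). This range is nested in subline, so it could not be a term of a model, and within-range comparisons were made instead.

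Per the submitters' processing notes, which name tools without their roles, Trim Galore 0.6.5, STAR 2.7.3a, RSEM 1.3.2, Picard 2.22.3 and GATK were used, with the builds GRCm38 and mm10. The authors deposited expected counts per gene, estimated read numbers that are not scaled for depth. The authors also deposited TPM values, which sum to 1000000 in each tumour, and FPKM values, which are scaled for length and depth. A deposited list of variants gives another kind of value, a position, a base change, a consequence class and a gene, with no column that names a tumour. The annotation release, strandedness, variant caller and filters are not given in the sources used here. Expected counts share reads among near-identical genes, so levels of single members of the immunoglobulin, haemoglobin, keratin-associated, H2 and Tgtp families are uncertain, as are those of overlapping and antisense genes.

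Expected counts were rounded to whole numbers. The table holds 55401 genes, and 17553 passed edgeR's filter by expression within sublines. Total counts ran from 17.8 to 24.2 x 1000000 per tumour, with a median of 20.3 x 1000000. Library sizes were scaled by TMM, and edgeR 4.0.16 fitted a quasi-likelihood model over all 33 tumours in R 4.3.3. An F test asked whether a gene differed among the 11 sublines. Then 11 contrasts set each subline against the unweighted mean of the other 10, and 55 contrasts compared pairs of sublines. Benjamini-Hochberg adjustment was made within each contrast, with a threshold of 0.05. Levels are given as counts per 1000000 (CPM) with the SD over 3 tumours, and log2 fold changes with an SE. This SE is an approximation, the absolute log2 fold change divided by the square root of its F statistic. A fold against sublines with 0 counts is a lower bound against a floor of 3 counts per tumour at the mean scaled library size of the subline, and covers counting error only. A fitted fold change of a gene with 0 counts in a whole subline depends on edgeR's default prior count. A prior count of 2 was used for log2 CPM only.

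A total of 34 gene lists were fixed before the data were examined, as were the tests, most of the other settings and the rule for named genes. A list score is the mean over its detected members of centred log2 CPM. Scores were compared among sublines by permuting subline names over tumours (100000 resamples, 10000 with a tumour left out, one-sided on the F statistic), with Benjamini-Hochberg adjustment over lists. For 32 of the lists, camera in limma 3.58.1 was run per contrast with a preset correlation of 0.01 and again with an estimated correlation. Beside each count of members past the threshold over all genes stands the count adjusted over the list alone. The rule named the 10 genes past the F test with the largest gap between the highest and lowest subline, with a mean of at least 5 CPM and no overlap between those 2 sublines, and per subline the 3 genes highest and the 3 lowest in log2 fold change with at least 1 CPM, leaving out predicted genes, receptor and immunoglobulin segments and pseudogenes. Members of the fixed lists could also be named. Which members are quoted was chosen after their values were seen. Gene positions are from GENCODE M21 on GRCm38, in which 55141 of the 55401 gene IDs were found ignoring the version.

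The gene model was tested on simulated counts with known changes. For C1 against the other 10, it recovered 14% of genes changed by 1.5-fold, 44% by 2-fold, 77.1% by 4-fold and 84% by 8-fold, with 12 false calls among 17498 genes. For C11 these shares were 16%, 46%, 72% and 86%, with 16 false calls among 17517 genes. The 12 false calls in C1 stood beside 7, 22, 37 and 42 genes recovered at these folds. The 16 in C11 stood beside 8, 23, 36 and 43. Set against the calls rather than the genes tested, the false share was above the adjusted p threshold in both comparisons. Genes were simulated independently of each other. The false calls therefore leave out variation that many genes share across tumours, and may be more frequent in the real data. Changes of 2-fold or less were thus often missed with 3 tumours per subline.

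Alternatives were another scaling, 2 other filters, DESeq2 1.42.0, limma-voom, a leukocyte score as a covariate, references within the title number range, a 2-fold threshold, TPM or FPKM in place of CPM, and leaving out each tumour or subline. The alternatives added after the data were seen were a reference without C11 and C23, leaving out the 2 tumours richest in keratinocyte genes, and leaving out the 3 tumours that lacked Y-linked counts while both siblings had over 200. C23_317 also had none, but is not among these 3, since a sibling had only 48. The planned comparisons of mutations between tumours were not run, because the variant list names no tumour. Python 3.11.15 with scipy 1.17.1 was used for scores and permutations.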

Results

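The data are bulk RNA-seq profiles of 33 tumours from 11 single-cell-derived sublines of B2905, a melanoma line from a mouse model in which tumours follow ultraviolet exposure. The design asks how tumours grown from sister clones of one line differ in gene expression. Each subline (C1, C4, C8, C11, C12, C14, C15, C16, C18, C22 and C23) gave 3 tumours, and total counts ran from 17.8 to 24.2 x 1000000 per tumour. Spearman correlations of log2 CPM between tumours of a subline averaged 0.962 (0.884 to 0.992), against 0.933 between sublines. As a check for libraries entered more than once, the lowest chi-square per degree of freedom between tumours of a subline was 8.61, in C15, which is set against sampling error alone and says nothing about biology.

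Expression differed widely among the sublines. Of 17553 genes tested, 10603 (60.4%) passed edgeR's F test. The median share of a gene's variance that lay between sublines was 38% (jackknife SE 7.4 percentage points). The genes with the widest gaps included the embryonic myosin Myh3, the muscle regulator Myog, the imprinted genes H19 and Igf2, Acta1 and Mybph, all highest in C11. The others were the immunoglobulin constant gene Ighg1 and the Y-linked Ddx3y and Eif2s3y, highest in C1, and 2310057J18Rik, highest in C12 at 500 ± 346 CPM (SD, n = 3). Within title number ranges, genes differing among the 11 sublines by this test numbered 4674 among the 7 sublines of the low range and 8205 among the 4 of the high range.

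Tumours resembled their siblings in part. For 21 of 33 tumours the nearest profile was a tumour of the same subline (one-sided permutation p = 1e-05, the smallest possible). The exceptions were all tumours of C4, C8 and C12, with C1_481, C11_508 and C23_318. Over 55 pairs of sublines the median number of genes past the threshold was 1018, and it reached 6648 for C11 against C18. No gene passed for C15 against C18 with edgeR or limma-voom, yet 3125 genes had an unadjusted p under 0.05, where 878 would by chance, and DESeq2 called 659.

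Pigment genes set C11 and C23 apart from the other sublines. Dct, a melanin synthesis enzyme (chromosome 14, 118012790 to 118052244), stood at 12.9 ± 9.65 CPM in C11 and 53.2 ± 62.7 in C23 (SD, n = 3), against 11300 ± 1050 in C15. Pmel, a melanosome matrix protein, stood at 8.69 ± 6.41 and 29.7 ± 38.1 CPM, and Mitf, the master regulator of melanocytes, at 53.4 ± 27.5 and 39.1 ± 6.06. Of 21 pigmentation genes, 19 fell in C11 and 17 in C23 (also 19 and 17 adjusted over the list alone). Dct fell by 8.45 ± 1.08 on the log2 scale in C11 and by 6.21 ± 0.96 in C23, with adjusted p = 1.82e-06 and 4.55e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Sox10, a neural crest factor, fell by 1.99 ± 0.29 in C11. In C23 its change of -0.39 ± 0.25 did not pass. The score of the list differed among sublines (F = 20.9, permutation adjusted p = 0.00034).

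**Figure D1:**
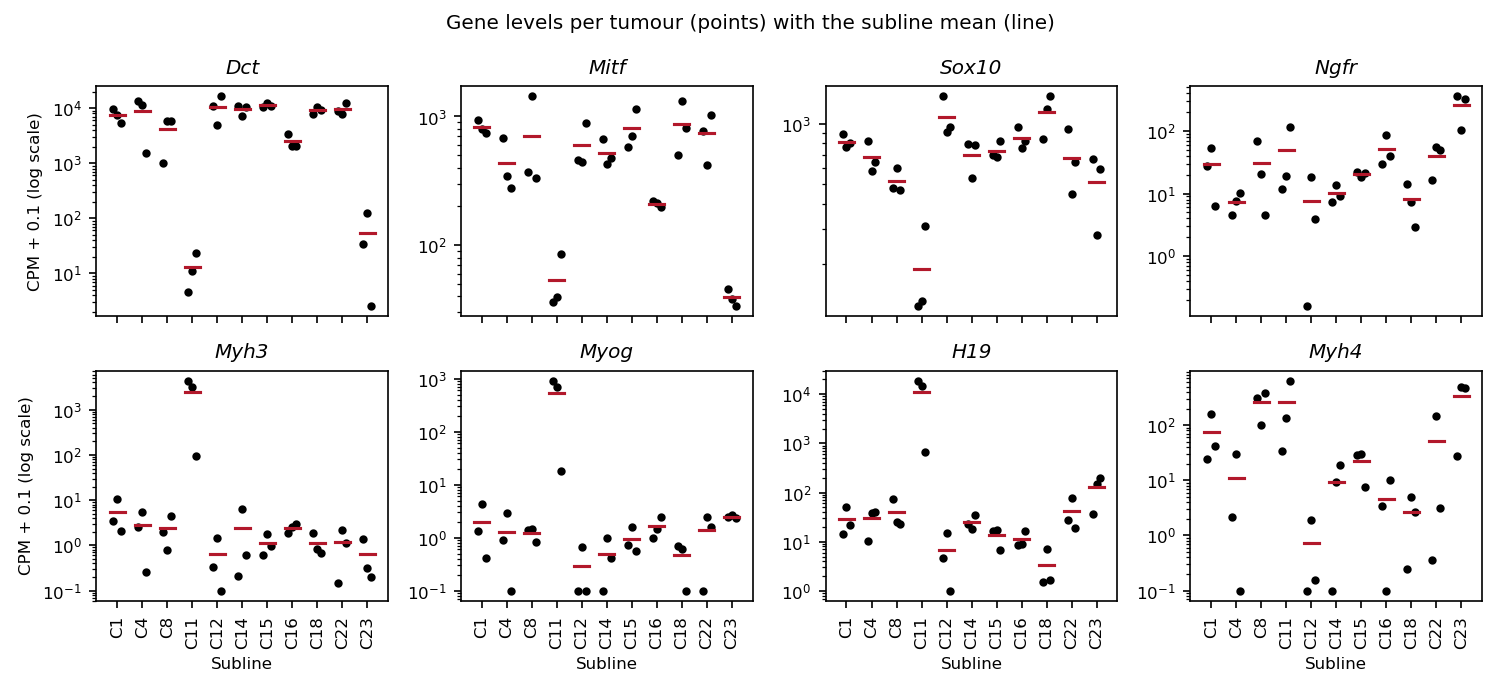
Levels of 8 genes in each tumour (points; CPM + 0.1 on a log axis) with the mean of the 3 tumours (red line), by subline on the horizontal axis. Dct and Mitf are low in C11 and C23, Ngfr is highest in C23, and Myh3, Myog and H19 are high in C11, where tumour C11_508 lies below the other 2.

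C11 tumours carried muscle transcripts. Myh3 (chromosome 11, 67078300 to 67102291) reached 2490 ± 2160 CPM in C11 (SD, n = 3), with 4280, 3100 and 95.9 CPM in tumours C11_502, C11_506 and C11_508, against at most 5.31 CPM in the mean of any other subline. Myog stood at 541 ± 463 CPM, Acta1 at 3560 ± 2470, Igf2 at 1280 ± 1090 and H19 (chromosome 7, 142575529 to 142578143) at 11200 ± 9350. Of 10 skeletal muscle genes, 9 rose (10 adjusted over the list alone). The adult fast myosin Myh4 ran the other way among these tumours, at 34.2, 135 and 626 CPM. Myh3 rose by 10.67 ± 0.58 on the log2 scale with adjusted p = 5.4e-13 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

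Markers of other cells also differed in C11. Of 18 macrophage genes, 15 rose (15 adjusted over the list alone), with Csf1r at 193 ± 92.6 CPM. Of 17 fibroblast genes 9 rose (14), of 8 keratinocyte genes 8 (8), and of 9 adipocyte genes 7 (8). Of 8 neutrophil genes 5 rose and 1 fell (5 and 1), while 3 of 5 erythroid genes fell (4). Axl, a receptor linked to dedifferentiated melanoma, stood at 598 ± 94.3 CPM, and 7 of 21 dedifferentiation genes rose (7). Ctrb1 and Otog, named by rule, were at 38.7 ± 34 and 17.5 ± 14.6 CPM against 0 in 7 sublines. Gulo and C87414 had 0 counts in C11, at least 93.6-fold and 79.3-fold below the mean of the others. Kcnj13 had 1 count. In total 3258 of the 17553 genes tested rose and 2630 fell, and the list counts of C11 are to be read beside these totals. The number past the threshold was 3872 or 3833 without tumour C11_502 or C11_506, and 2978 with a leukocyte covariate. Without tumour C11_508 Cd163 and Adipoq turned lower, at -0.74 and -1.28 on the log2 scale, with neither past the threshold, and Csf1r, Col3a1, Lep and Myh4 no longer passed.

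C23 combined low pigment genes with higher matrix genes and part of the dedifferentiation genes. Ngfr, a nerve growth factor receptor (chromosome 11, 95568818 to 95587735), stood at 357, 102 and 330 CPM in tumours C23_317, C23_318 and C23_319 (SD 140, n = 3), with no other subline mean above 51.5. Egfr was at 76.4 ± 24.8 and Gfra2 at 70.7 ± 41.2 CPM. Of 21 dedifferentiation genes 10 rose and 1 fell (10 and 1 adjusted over the list alone). Of 17 fibroblast genes 14 rose (16), with Col3a1 at 5460 ± 3000 CPM and Lum at 397 ± 324, and of 10 muscle genes 8 rose (10). Genes of oxidative phosphorylation fell, 21 of 25 (25), with Ndufa4 at 114 ± 1.65 CPM. So did 11 of 16 cholesterol synthesis genes (14) and 5 of 5 erythroid genes (5). Of 8 neutrophil genes 4 rose and 1 fell (5 and 1), and of 10 dendritic cell genes 3 rose (3). Ngfr rose by 3.74 ± 0.54 on the log2 scale with adjusted p = 2.08e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

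Some values of C23 rested on tumour C23_318. All 8 keratinocyte genes rose (8 adjusted over the list alone), yet Krt14 was at 0, 3230 and 4.36 CPM in tumours C23_317, C23_318 and C23_319. Without tumour C23_318 its change of 9.32 ± 1.12 on the log2 scale did not pass, nor did those of Krt5, Alox12e, Fcgbp and Epha4. Krt10 was at 157 ± 269 CPM (SD, n = 3). Among MAPK output genes 6 of 14 fell and 1 rose (6 and 2 adjusted over the list alone), with Dusp6 at 132 ± 23 CPM. Kcnn2 had 1 count, Igfn1 11 counts and Scn10a none, at least 36.5-fold below the mean of the others. In total 2938 of the 17553 genes tested rose and 2261 fell, and the list counts of C23 are to be read beside these totals. The number past the threshold was 2984 without tumour C23_318.

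C1 tumours had high levels of part of the T cell, B cell and plasma cell genes, least so in C1_481. Ighg1 (chromosome 12, 113325240 to 113330523) stood at 306 ± 106 CPM (SD, n = 3), against at most 12.6 CPM in the mean of another subline. The plasma cell genes Jchain and Mzb1 stood at 77.1 ± 56.2 and 4.02 ± 2.93 CPM, the T cell coreceptor Cd8a at 14.4 ± 12.3 and the interferon-induced chemokine Cxcl9 at 227 ± 203. Of 19 T cell genes 6 rose (17 adjusted over the list alone), of 20 interferon gamma response genes 8 (16), of 8 MHC class II genes 5 (8), of 7 B and plasma cell genes 5 (5) and of 14 cytotoxic or exhaustion genes 5 (10). Of 8 natural killer genes 0 rose (1), and of 7 regulatory T cell genes 0 (0). In tumours C1_478, C1_480 and C1_481 Cd8a was at 10.8, 28 and 4.27 CPM, Cxcl9 at 171, 452 and 58.3 and Jchain at 96.7, 121 and 13.8. Ighg1 rose by 8.16 ± 0.72 on the log2 scale with adjusted p = 1.32e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

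Other genes named by rule in C1 were Snorc at 7.11 ± 9.07 CPM, Uba1y at 10.7 ± 6.05 and Rxfp1 at 3.92 ± 3.60 (SD, n = 3), with Magea8, Car9 and Tubb3 lower. Rxfp1 was not highest in C1, since C14 stood at 35.7 CPM. Its mean CPM in C1 was 1.09 times that of the other sublines, 6 of which had 0 counts. In total 613 genes rose and 68 fell in C1. Leaving out tumour C1_478, C1_480 or C1_481 left 302, 421 or 397 genes, and a leukocyte covariate gave 1139. Without tumour C1_480 Cd8a, Cd3e, Cxcl9, Cd74 and Pdcd1 no longer passed.

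C12 tumours stood low in part of the T cell, antigen presentation, other leukocyte, muscle and proliferation genes. Cd74, the class II invariant chain, was at 98.2 ± 86.2 CPM (SD, n = 3), H2-Aa at 42.4 ± 36.1 and the T cell gene Cd2 at 0.304 ± 0.265. Of 19 T cell genes 9 fell (13 adjusted over the list alone), of 8 MHC class II genes 7 (7), of 17 MHC class I genes 8 (9), of 20 interferon gamma response genes 7 (10), of 10 muscle genes 5 (10) and of 8 natural killer genes 3 (6). Of 18 macrophage genes 5 fell (8), of 14 pan-leukocyte genes 4 (7), of 10 dendritic cell genes 2 (2) and of 16 proliferation genes 4 (7). Of 14 cytotoxic or exhaustion genes 1 fell (1), and of 7 B and plasma cell genes 0 (0). Cd74 fell by 2.86 ± 0.78 on the log2 scale with adjusted p = 0.0159 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Diras2, Prb1 and Prpmp5 were higher than the mean of the others, at 104 ± 82.1, 35.9 ± 60.7 and 22.5 ± 34.4 CPM. None was highest in C12: Diras2 reached 116 CPM in C16, and Prb1 and Prpmp5 reached 42.4 and 95.4 in C14. Prox1 and Rgs7bp had 0 counts, at least 18.3-fold and 13.1-fold below the mean of the others, while Pvalb had 1 count. In total 1827 genes rose and 876 fell. Without tumour C12_263 the count was 920 and Cd74, Cd2, Cd3e and H2-Aa no longer passed, and with a leukocyte covariate it was 412.

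C16 tumours had high levels of part of the type I interferon response and MHC class I genes. B2m, the MHC class I light chain (chromosome 2, 122147686 to 122153083), stood at 5150 ± 974 CPM (SD, n = 3), Bst2 at 497 ± 73.3, Oas2 at 88.5 ± 68.5 and Ifit3 at 199 ± 57.1. Of 20 type I interferon response genes 7 rose (16 adjusted over the list alone), and of 17 MHC class I genes 7 rose (9), while 0 of 20 interferon gamma response genes rose (0). In C11 6 of 20 type I interferon response genes rose (6), where 3258 of all 17553 genes tested did. The melanosome transporter Slc45a2 was at 12 ± 3.20 CPM, while 1 of 21 pigmentation genes fell and 1 rose (1 and 1). B2m rose by 1.27 ± 0.17 on the log2 scale with adjusted p = 2.43e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Csn3, a milk casein, stood at 204 ± 190 CPM, Wfdc18 at 73.2 ± 64.3 and Cpa4 at 44.3 ± 75.0, the last at 0.924, 131 and 1.12 CPM per tumour and not past the threshold without tumour C16_282. Vsnl1 had 0 counts, at least 10.3-fold below the mean of the others, Ptprz1 had 3 and Hs3st3a1 had 1. In total 1057 genes rose and 453 fell, with 700, 720 and 885 left without tumour C16_281, C16_282 or C16_285.

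C18 tumours were higher in respiratory chain genes and in interferon gamma genes, whose score was highest in C18_292. Ndufb3, a complex I subunit, stood at 169 ± 64.2 CPM (SD, n = 3), Cox6c at 547 ± 290 and Psmb9, an immunoproteasome subunit, at 121 ± 34.3. Of 25 oxidative phosphorylation genes 16 rose (20 adjusted over the list alone), of 20 interferon gamma response genes 10 (14) and of 17 MHC class I genes 8 (10). The GTPase Tgtp1 was at 246, 39.4 and 18.1 CPM in tumours C18_292, C18_293 and C18_295. Of 14 cytotoxic or exhaustion genes 2 rose (5), while Ifng was at 2.55, 0.257 and 0.472 CPM and Gzmk at 2.55, 0.565 and 0.649 in these tumours. Ndufb3 rose by 1.18 ± 0.18 on the log2 scale with adjusted p = 0.000235 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Hoxa10 and B4galnt3 were lower and Ehf had 0 counts, at least 9.74-fold below the mean of the others. In total 1712 genes rose and 690 fell. Without tumour C18_295 or C18_293 the count was 135 or 723, and Cox6c no longer passed without C18_295. Without C18_292 Tgtp1, Ifng and Gzmk did not pass, nor did Ifng and Gzmk without C18_295.

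C14 and C15 were high in pigment genes against a mean that includes C11 and C23. Pmel stood at 6640 ± 874 CPM in C14 and 4580 ± 688 in C15, and Dct at 9470 ± 2000 and 11300 ± 1050 (SD, n = 3). Of 21 pigmentation genes 11 rose in C14 (13 adjusted over the list alone) and 9 in C15 (15), as did 11 in C12 (14), 9 in C18 (14), 6 in C4 (10), 5 in C1 (12) and 4 in C22 (9). With C11 and C23 left out of the reference, 1 rose in C14, 1 in C12 and 0 in each of C15, C18, C4, C1 and C22. Rxfp1, the relaxin receptor, was at 35.7 ± 36.7 CPM in C14, and Prpmp5 at 95.4 ± 78.5. Phyhipl was at 93.1 ± 15.2 CPM in C15 and 135 ± 66.2 in C18, Aass at 17.1 ± 3.34 and 10.7 ± 2.40 and Dcaf8l at 11.6 ± 4.89 and 6.73 ± 2.09. Pmel rose by 2.62 ± 0.48 on the log2 scale in C14 with adjusted p = 0.0015 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Crabp2, Aqp5 and Hoxa10 were lower in C15, and Tph2, Nkain2 and Cfap61 had 1 count each in C14. In total 793 genes rose and 423 fell in C14, and 706 and 148 in C15. Without tumour C14_543, C14_544 or C14_551 the C14 count was 353, 505 or lower by 898. Without tumour C15_560, C15_561 or C15_578 that of C15 was 119, 96 or 152, and without C14_543 it was 562.

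C4, C8 and C22 differed from the rest by fewer genes or through single tumours. In C4 the endoplasmic reticulum chaperone Hspa5 stood at 1180 ± 411 CPM (SD, n = 3) and Pdia4 at 727 ± 327, and 3 of 11 unfolded protein response genes rose (8 adjusted over the list alone). In C8 Krt27 was at 14.3, 0.160 and 448 CPM in tumours C8_241, C8_244 and C8_245. There 6 of 8 keratinocyte genes (6) and 5 of 10 muscle genes (8) rose, but Krt27, Krt5, Trp63, Myh4 and Ckm did not pass without C8_245. In C22 Zfp811 stood at 18.3 ± 6.60 CPM, with no other subline above 0.518, and B2m at 1380 ± 167, with 2 of 17 MHC class I genes lower (5), neither past the threshold once any C22 tumour was left out. Zfp811 rose by 6.59 ± 0.35 on the log2 scale with adjusted p = 5.02e-12 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Also named by rule were Hhla1, Scg2, Hkdc1, Igflr1, Nptx2 and Crabp1 in C4, Krtap8-1, Krtap11-1, Veph1 and Phyhipl in C8, and Insc, Penk, Tbx20, H4c8 and Zfp518b in C22. In C4, C8 and C22, 593, 814 and 291 genes rose and 111, 224 and 82 fell. Without tumour C4_223 or C4_225 the C4 count was 336 or lower by 411, and Hspa5, Pdia4 and Dnajb9 did not pass without C4_225. Without tumour C8_245 the C8 count was lower by 743, and without C22_311, C22_313 or C22_315 that of C22 was 188, 170 or 165.

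**Figure D2:**
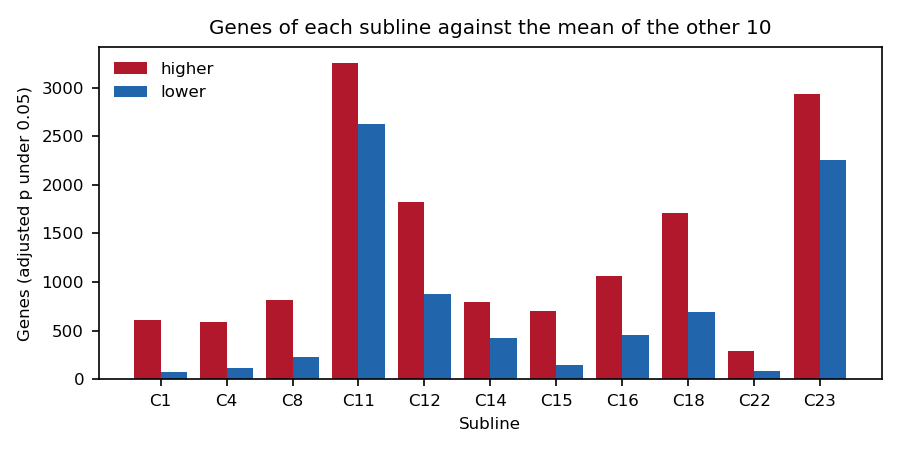
Bars give the number of genes higher (red) and lower (blue) in each subline against the mean of the other 10, at adjusted p under 0.05. C11 (3258 higher, 2630 lower) and C23 (2938 and 2261) have the most, and C22 (291 and 82) the fewest.

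Scores of 20 of the 34 lists differed among sublines by permutation. After pigmentation came MHC class I (adjusted p = 0.00782), erythroid and sex-linked genes (0.00994), and skeletal muscle, fibroblast, MHC class II and oxidative phosphorylation genes (0.0119). Dedifferentiation genes followed (0.0145), then interferon gamma, B and plasma cell, neutrophil, p53 target and melanoma driver genes (0.0319), T cell, macrophage, dendritic and TGF-beta genes (0.0362), pan-leukocyte genes (0.041) and regulatory T cell genes (0.0447). Not past the threshold were checkpoint ligand, natural killer and cholesterol genes (0.0614), endothelial (0.0753), keratinocyte (0.0776), type I interferon and adipocyte (0.0825), cytotoxic and proliferation (0.0847), Wnt (0.0885), MAPK (0.203), unfolded protein response (0.213), glandular (0.432) and hypoxia genes (0.649). On TPM values 14 lists passed. Fewer passed without C1_478 (12), C23_319 (9), or C11_506, C12_263, C15_561, C18_293 or C23_317 (13 each). In camera 108 of 352 list-by-subline tests passed with a preset correlation and 0 with an estimated one, where adjusted p = 0.497 with an estimated correlation for pigmentation in C11 and C23.

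**Figure D3:**
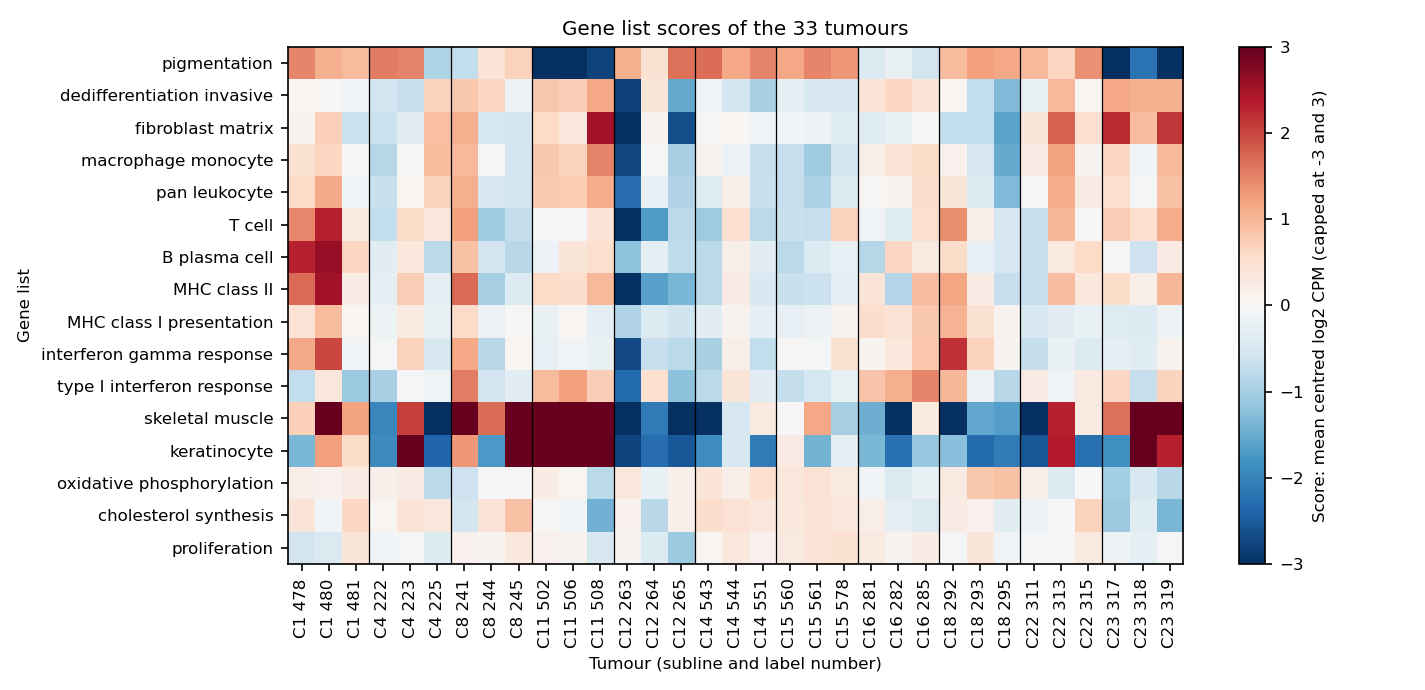
Colours give the score of 16 gene lists (vertical axis) in each of the 33 tumours (horizontal axis, grouped by subline), as mean centred log2 CPM capped at -3 and 3. The pigmentation score is lowest in C11 and C23, with subline means of -3.82 and -3.67.

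Over the 11 sublines, 8 list scores were set against the T cell score. The interferon gamma score had r = 0.794 (permutation p = 0.00621, adjusted p = 0.0497) and Spearman's rho = 0.5 (permutation adjusted p = 0.327). It rested on C1 and C12, since r was 0.252 without both, and in the 7 sublines of the lower number range it was 0.733 (exact permutation p = 0.0944). The adjusted p no longer passed when any 1 of 10 sublines was left out, C23 being the exception. Fibroblast (r = 0.661), macrophage (0.637), dedifferentiation (0.596), MHC class I (0.579) and hypoxia (-0.567) scores had a permutation adjusted p = 0.0906, and pigmentation (-0.26, 0.448) and proliferation (0.158, 0.649) were farther from the threshold.

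Y-linked genes were undetected in 10 tumours. The summed counts of Ddx3y, Eif2s3y, Kdm5d and Uty were 0 in all tumours of C11 and C22 and in C8_241, C12_263, C16_285 and C23_317. In 22 tumours they were over 200, at most 10792, and in C23_318 they were 48. Ddx3y (chromosome Y, 1260771 to 1286629) stood at 185 ± 38.2 CPM in C1 and Eif2s3y at 119 ± 15.2 (SD, n = 3). Xist, transcribed from the inactive X chromosome of female cells, ran from 24.9 to 377 CPM. Ddx3y rose in C1 by 4.94 ± 0.96 on the log2 scale with adjusted p = 0.00408 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. As a ratio of mean CPM the difference was 4.95, with C4 next at 82.6 CPM. The larger log2 value averages over sublines with 0 counts. With C11 and C23 left out of the reference Ddx3y did not pass, though C22, with 0 counts, stayed in that reference.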

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

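Tests on the label swap, the title number range and the splits for pairs and lists were set before their results were seen. All other tests here were chosen after the result was seen, and so was the part of the muscle test that covers 2 tumours.

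The variant list, which no comparison used, holds 13441 distinct variants. It was singled out as a signal outside the expression values, with no level in control samples to set it against. Single-base changes were pooled with their complements, so T to C also holds A to G, and C to T also holds G to A. In these pooled classes, 33.3% of 10592 single-base variants were T to C and 31.2% C to T. Of all distinct variants, 14.6% lay in immunoglobulin variable genes.

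Muscle genes in C11 may come from host muscle or from the tumour cells, and the second was not tested. If adult muscle were the source, the ratio of Myh3 to Ckm should match that of other tumours. Over all 3 tumours the lowest ratio was 1.93 times the highest outside C11, short of the bound of 2 set for that test, so adult muscle cannot be told apart for C11 as a whole. A further test on tumours C11_502 and C11_506 alone was added after that bound was missed, and there the lowest ratio was 120 times the highest outside C11, which argues against adult muscle in those 2. For immature host muscle, Xist in tumour C11_508, lowest in Myh3, was 2.64 times the mean of the other 2, and 3 tumours are too few to decide.

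Tumours C8_241, C12_263 and C16_285 had no Y-linked counts although both siblings had over 200, a limit set after the counts were seen. C23_317 also had none, with 48 in a sibling, and was left out of these tests. A lower share of tumour cells would need few expected counts, but Sox10 and the siblings predicted at least 459 Ddx3y counts in each, with 0 seen. A tumour of another subline under these labels cannot be told apart: 2 of the 3 matched their own subline best over autosomal genes, C8_241 matched C23 best, and over all tumours only 21 of 33 matched their own. Loss of the Y chromosome in part of a subline stays open as a hypothesis and was not tested.

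Pigment genes were low in C11 and C23. Dilution of tumour RNA by other cells should lower them about as much as Sox10, but 13 of 20 members in C11 and 17 of 20 in C23 lay below Sox10 by more than 2 SE. A batch that follows the 2 title number ranges is argued against by at least 17 of 21 members called lower in both sublines against sublines of their own range. Within a range the title numbers run in blocks by subline, so a finer batch cannot be told apart from subline. A difference between the clones may account for it, as a hypothesis found and tested on the same data.

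Other assignments of the 33 tumours to 11 groups of 3 were drawn, 100 in all with the real one. Their number was first 60 and was raised to 100, the most allowed, after the outcome with 60 had been seen. Chance was excluded for the F test (10603 genes, highest other 1289) and for C11 (5888, 3489) and C23 (5199, 1534). Each had 1 of 100 as large, the real one included. C12 (2703, 929), C16 (1510, 1476) and C18 (2402, 2030) also had 1 of 100 under their own names. Names are interchangeable in a drawn split, and 1 drawn group reached 3489 genes, above every real count but those of C11 and C23. Chance was thus not excluded for C12, C16 and C18 when all 11 sublines are considered. C4 (704, 2074) and C14 (1216, 1588) had 4 of 100, under 5%, but 3 of the first 60, which is not, so both are borderline and depend on that change. C8 (1038, 1432) had 5 of 100, and 3 of 60. Chance was also not excluded for C1 (681, 2354; 7 of 100), C15 (854, 2099; 6) and C22 (373, 1006; 12). Single splits gave more genes than the real group, which might reflect a structure of the samples. A drawn group could gather tumours of C11 or C23, so these counts need not reflect chance alone. Which tumours those splits grouped was not examined, so for the other sublines the splits do not decide. For pairs of sublines 1 of 30 splits was as large (1018, highest other 0), so chance was excluded there. For camera 29 of 30 gave as many lists (108, highest other 163), so chance was not excluded and those list calls carry no weight.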

How the results depend on the processing

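The reference without C11 and C23 and the fits without keratinocyte-rich or Y-lacking tumours were chosen after the data were seen. Other settings were planned. Values written with an exponent are rounded to 2 digits. Main counts stand in the report, and the cause of each move was not tested unless named. Of 171 gene results, 77 were unchanged in call and direction in all settings. The other scaling changed none, DESeq2 weakened 11, limma-voom 43, the leukocyte covariate 33, and leaving out some tumour 75. Cd163 and Adipoq in C11 turned to -0.74 and -1.28 without C11_508, and were 2.78 and 3.03 at most without another tumour of C11. Calls of Aqp5 in C15, Crabp1 and Nptx2 in C4, Ehf in C18, Gulo in C11 and Scn10a in C23 were lost in many settings.

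With no filter C15 had 483 genes, C18 1564 and the median pair 618. With DESeq2 C14 had 1949, C15 1484 and the median pair 2047, and its share of higher calls was lower in 9 of 11 sublines: 74.2% against 90% in C1, 71.2% against 84.2% in C4, 61.9% against 78.4% in C8, 51.8% against 67.6% in C12, 46.3% against 65.2% in C14, 54.5% against 82.7% in C15, 52.3% against 70% in C16, 48.9% against 71.3% in C18 and 59.2% against 78% in C22. It was 55.9% against 55.3% in C11 and 56.7% against 56.5% in C23. With limma-voom C8 had 3.0e+02. With a leukocyte covariate C1 had 1139, C11 2978, C12 412 and C18 1363. With the reference within the number range C15 had 1348. Among the 7 sublines of the low range 4674 genes passed the F test. That fit has fewer samples and also leaves out C1, C11, C14 and C15, and their effects were not told apart. With an estimated correlation 0 list calls were left of 108. At 2-fold or more, a stricter rule by construction, C4 had 447 genes, C11 3349, C12 1540, C14 5.0e+02, C15 288, C16 653, C18 758, C22 202 and C23 3096.

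With C11 and C23 out of the reference C4 had 341 genes, C8 1936, C12 1524, C14 753, C15 428 and C18 967. Without C8_245 and C23_318, the keratinocyte-rich tumours, C8 had 340 and C23 3028. Without C8_241, C12_263 and C16_285, which lack Y-linked counts, C12 had 926.

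Leaving out each tumour in turn gave 302 to 962 genes for C1, 2.9e+02 to 962 for C4, 3.0e+02 to 1425 for C8, 3833 to 6373 for C11, 920 to 3646 for C12, 3.2e+02 to 1613 for C14, 96 to 1093 for C15, 700 to 1832 for C16, 135 to 3142 for C18, 165 to 546 for C22 and 2984 to 5799 for C23, where the report names each tumour that lowers a count by over 1.5 times. It gave 9649 to 11605 genes for the F test, 688 to 1282 for the median pair, 101 to 124 camera calls, 9 to 25 list scores, 18 to 22 nearest tumours and 35.8 to 41.1% of variance. Against the T cell score, interferon gamma had r from 0.577 to 0.871 with 1 subline left out and an adjusted p over the threshold without any of C1, C4, C8, C11, C12, C14, C15, C16, C18 or C22 (0.719, 0.794, 0.803, 0.801, 0.577, 0.785, 0.805, 0.809, 0.83 and 0.823).

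The planned mutation alternatives were not run, as the variant list names no tumour. No paired analysis was possible because title numbers are not shared between sublines. With 3 tumours per subline and about 20.3 x 1000000 counts, most 1.5-fold changes would be missed.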

Other observations

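The test of Xist below was set before its result was seen. Xist level differed among tumours, and a hypothesis is that it comes from host cells of female mice, whose share of the sample differs. Over 33 tumours log2 CPM of Xist and the mean score of 4 host cell lists had r = 0.805 and rho = 0.737 (permutation p = 1e-05 for each, the smallest possible). Without the 2 tumours farthest from the median r was 0.717, and within the number ranges it was 0.808 (n = 21) and 0.823 (n = 12). After subline means were removed r was 0.721. These values are in line with that hypothesis, but the sex of the mice was not used here and host cell shares were not measured otherwise.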
